A study of Homo sapiens with 6 samples.

How the data were processed

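MCF-7 cells, an established estrogen receptor positive line of luminal breast cancer cells, were transfected with Lipofectamine. 3 samples received a scrambled control siRNA and 3 received an siRNA of 1 sequence against MYO6, the gene of the actin motor myosin VI, and RNA was taken after 48 h, per the labels' protocols. RNA was extracted with TRIzol, poly(A)-selected and sequenced as paired reads on a HiSeq, per the labels' protocols. All 6 libraries were used, and each took its group from its sample title. The control samples are titled WT Control, so their scrambled siRNA is known from the protocol text only. If they were not transfected, effects of transfection could not be told apart from those of the MYO6 siRNA. The labels do not say whether replicates were separate cultures on separate days, so the p-values measure the spread between these samples, which may be technical.

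The authors deposited, for each library, a table of 178136 transcripts with the transcript length, an effective length, an estimated count and a TPM value, per the file headers. The estimated counts need not be whole and are not normalized, whereas the deposited TPM values are scaled to transcript length and to the same sum in every library. The submitters' processing notes name Trimmomatic 0.36, STAR 2.5.2b, featureCounts, Subread 1.5.2 and GRCh38. Estimated counts and effective lengths per transcript are not what featureCounts writes, so which program made the deposited tables, and with which settings, is not given in the sources used here. Such estimates share reads between transcripts of similar sequence, so values of near-identical genes and of single isoforms are uncertain. Whether the libraries or the counting used strand is not given either, so reads of overlapping antisense genes may not be told apart.

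Transcript identifiers were matched to GENCODE release 29 on GRCh38. 162410 transcripts (91.2%) matched, 98.3% of them with the same length, and they held 97.76% to 97.86% of each library's estimated counts. Counts were summed over the transcripts of each of 35040 genes and rounded to whole numbers. Symbols came from a gene name table for 34893 genes and from the annotation for the other 147. The 15726 unmatched transcripts stayed out of the gene totals and were tested on their own. Coordinates are 1-based positions of that annotation. The siRNA was placed by an exact search for its 19-base sense strand in the annotated transcripts.

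The libraries held between 27426654 and 36411789 estimated counts. The comparison of MYO6 siRNA with control siRNA used edgeR 4.0.16 in R 4.3.3, with TMM normalization, filterByExpr at its defaults (minimum count 10, minimum total 15) and the quasi-likelihood F test with group as the only term. Adjusted p-values are Benjamini-Hochberg values over all genes tested, with 0.05 as the threshold. CPM values, counts scaled to a common library total, use the TMM library sizes. The standard error of a log2 fold change was computed as its size divided by the square root of its F statistic. On counts simulated from these libraries for 14358 genes, with 100 genes changed by 1.2-fold and 100 by 1.5-fold, the test recovered 39% of the former and 72% of the latter. It called 9 unchanged genes beside them, and 1 gene when none was changed.

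29 gene lists and the rule for naming genes were fixed before the data were examined. The lists were tested with camera of limma 3.58.1 (preset inter-gene correlation 0.01), and p-values were adjusted over the 29 lists. Camera with an estimated correlation and fry were alternatives. The lists held estrogen-induced genes, luminal identity genes and receptor cofactors, myosin VI partners, other myosin heavy chains, RNA polymerase II and general factors, clathrin endocytosis, autophagy, lysosome, SRF and YAP targets, cell adhesion, epithelial to mesenchymal transition, interferon response, p53 targets, G1/S and DNA replication, G2/M and mitosis, hypoxia and glycolysis, unfolded protein response and ATF4 targets, cholesterol synthesis, heat shock proteins, NF-kB and inflammatory genes, cytosolic ribosomal proteins, nuclear and mitochondrially encoded respiratory chain genes, replication dependent histones, immediate early genes, RNA interference machinery, and markers of basal epithelium, fibroblasts, and leukocytes with endothelium. The rule named MYO6, the 12 largest rises and 12 largest falls, and up to 4 members of each list with the smallest p. A rise or fall had to be a protein-coding gene with an adjusted p under 0.05, a mean of at least 5 CPM and no overlap between the groups. Other genes named in the text were chosen after their values were seen.

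Alternatives were DESeq2 1.42.0, limma voom, limma with trend on log2(TPM + 1) and log2(TPM + 0.1) for genes of mean TPM of at least 1, other size factors, other count filters, unrounded counts, an offset for effective length, protein-coding genes alone, a block for the replicate number, and leaving out each library in turn. A 7-base match to positions 2 to 8 of the siRNA's guide strand was searched for in the annotated 3' UTR of each gene's main coding transcript. 100 other 7-mers of the same base composition served as controls. The seed calculation, tested on simulated fold changes for 14358 genes with a shift of 0.2 planted, gave -0.208, and -0.0085 with none planted. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.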

Results

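Poly(A) RNA was measured in 6 samples of MCF-7 cells, 3 transfected with a control siRNA and 3 with an siRNA against MYO6. The control libraries held 27426654, 36411789 and 29486894 estimated counts and the MYO6 siRNA libraries held 28963378, 33747195 and 33692116. After the filter on low counts, 14358 genes were tested. The first principal component of log2 CPM took 44.7% of the variance and separated the groups, with control libraries between -20.19 and -18.03 and MYO6 siRNA libraries between 16.83 and 20.85. Pairs of libraries within a group correlated at r = 0.99199 to 0.99445 across genes, and pairs between the groups at 0.9879 to 0.98927. Genes are not independent replicates, so these coefficients only describe the libraries.

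MYO6 itself was measured first, as a check of the labels. MYO6 (ENSG00000196586, chromosome 6, 75749192 to 75919537 on GRCh38) fell from 192.3 ± 11.2 CPM (SD, n = 3) with control siRNA to 39.4 ± 1.56 CPM (SD, n = 3) with MYO6 siRNA, which left 20.5% of the control level. The estimated counts were 5450, 6364 and 5714 in the control libraries and 1073, 1284 and 1344 in the MYO6 siRNA libraries. The log2 fold change was -2.29 ± 0.06 (SE), with an adjusted p of 1.39e-11 in edgeR's quasi-likelihood test, the smallest of all genes tested. In deposited TPM summed over transcripts, the level went from 50.4 ± 3.23 to 8.90 ± 0.55 (SD, n = 3 each), or 17.7% of control.

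The siRNA sense strand, GGUUUAGGUGUUAAUGAAG, matched 6 annotated transcripts exactly, all of them from MYO6. The site lies on chromosome 6 from 75861047 to 75861065 on the plus strand, in the coding sequence, within exon 14 or exon 15 depending on the transcript. The 2 transcripts with the highest TPM in control libraries both contain it. ENST00000369975 went from 20.5 ± 1.78 to 5.21 ± 0.31 TPM and ENST00000615563 from 21.9 ± 2.66 to 1.34 ± 0.84 TPM (SD, n = 3 each). These isoforms share most of their sequence, so the division of reads between them is an estimate and was not tested.

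**Figure D1:**
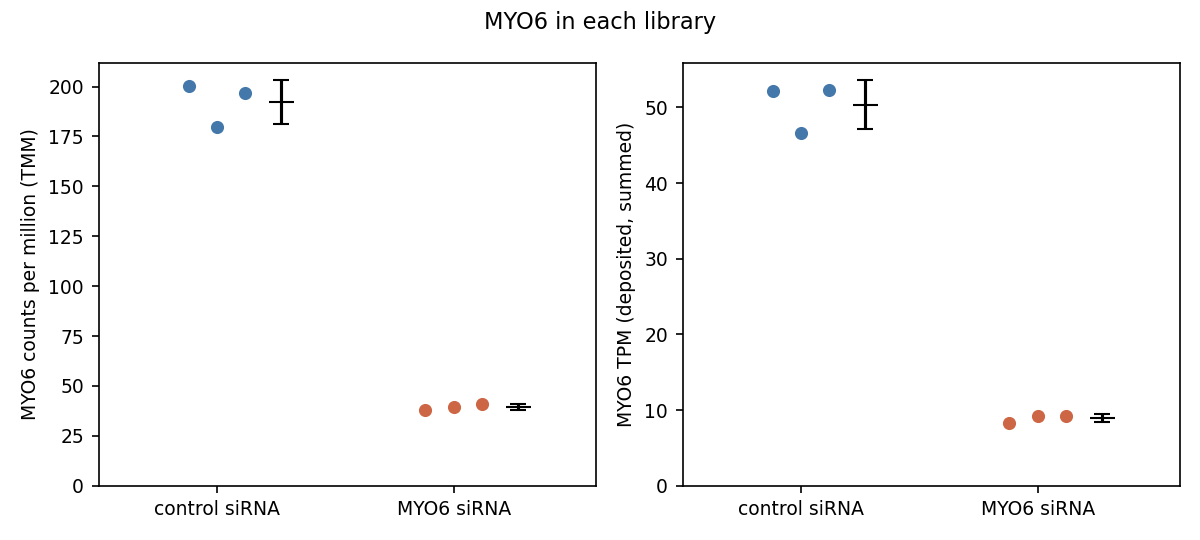
MYO6 in each of the 6 libraries, as TMM-scaled CPM (left axis panel) and as deposited TPM summed over transcripts (right axis panel). Points are libraries and the bars beside them are the mean and SD of 3; all MYO6 siRNA libraries lie between 37.9 and 41.02 CPM and all control libraries between 179.5 and 200.5 CPM.

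The question of the design was which transcripts change when myosin VI is depleted. Only RNA was measured here, so the level of myosin VI protein is not known. Among the genes that rose most, ATF3, a stress-induced transcription factor, rose 4.03-fold, FAS, a death receptor, 3.36-fold, and HMOX1, the heme-degrading enzyme, 3.14-fold. CDKN1A, which encodes the cyclin-dependent kinase inhibitor p21, rose from 244.5 ± 12.8 to 648.6 ± 26 CPM. Among the genes that fell most were ZNF185, an actin-associated LIM domain gene, and SUPT16H, a subunit of the histone chaperone FACT. In all, 4307 genes (30.0% of those tested) passed an adjusted p of 0.05 in edgeR, 2139 of them higher and 2168 lower with MYO6 siRNA.

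Most of these changes were small. The median absolute log2 fold change of the 4307 genes was 0.29, and 1868 of them (43.4%) changed by less than 1.2-fold. A change of at least 1.5-fold was found for 672 genes, 320 higher and 352 lower, and a change of at least 2-fold for 188, 108 higher and 80 lower. The 3 MYO6 siRNA values and the 3 control values did not overlap in 6155 genes, 42.9% of those tested, where chance gives 10%. Against a null of a 1.2-fold change, 819 genes passed, 370 higher and 449 lower. The effective length offset, which uses the deposited lengths, lowered the number of calls to 2427. Limma with trend on log2(TPM + 1), which also changed the test and the gene filter, gave 2051.

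Of the 12 largest rises among genes of at least 5 CPM, ATF3 (chromosome 1, 212565334 to 212620777) went from 4.63 ± 0.36 to 18.6 ± 0.21 CPM (log2 fold change 2.01 ± 0.08 SE, adjusted p 3.35e-09 in edgeR). FAS went from 2.49 ± 0.18 to 8.41 ± 1.36 CPM and HMOX1 from 8.78 ± 0.88 to 27.7 ± 1.2 CPM. CDKN1A (chromosome 6, 36676460 to 36687339) had a log2 fold change of 1.41 ± 0.05 (SE) and an adjusted p of 1.07e-09. GADD45A, a growth arrest gene, rose 2.62-fold and BBC3, which encodes the pro-apoptotic protein PUMA, 2.20-fold. GDF15, a secreted stress cytokine, rose 2.40-fold, from 24.9 ± 1.93 to 59.7 ± 2.81 CPM. The other rises were MEX3B, an RNA-binding protein gene, at 2.46-fold, the phosphatase gene DUSP13 at 2.34-fold, PEG10, a retrotransposon-derived gene, at 2.22-fold, SHANK3 at 2.18-fold and the pseudokinase gene STRADB at 2.16-fold. Adjusted p-values of these 12 genes were 0.00385 for SHANK3 and at most 4.76e-06, that of DUSP13, for the others. SHANK3 varied widely between libraries, with 9.66 ± 2.55 against 4.42 ± 1.90 CPM (SD, n = 3 each), and lost its call on log2(TPM + 1) with an adjusted p of 0.0561 in limma.

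Of the 12 largest falls below MYO6, ZNF185 (chromosome X, 152914442 to 152973480) went from 92.2 ± 3.99 to 35.8 ± 2.37 CPM, a log2 fold change of -1.36 ± 0.06 (SE) with an adjusted p of 3.35e-09 in edgeR. SUPT16H (chromosome 14, 21351472 to 21384266) went from 289.8 ± 6.57 to 126.3 ± 1.80 CPM, a log2 fold change of -1.198 ± 0.043 (SE) with an adjusted p of 1.07e-09. Its FACT partner SSRP1, looked up after these values were seen, went from 166.2 ± 5.68 to 150.6 ± 5.37 CPM, with an adjusted p of 0.0314 that was lost without any 1 of control replicate 3 and MYO6 siRNA replicates 1, 2 and 3 (0.0976, 0.157, 0.0513 and 0.0644). PAIP2, a regulator of poly(A)-binding protein, went from 97.1 ± 2.34 to 41.9 ± 1.09 CPM, and NDFIP1, an adaptor of Nedd4-family ubiquitin ligases, from 90.7 ± 4.41 to 38.3 ± 2.12 CPM. KIAA1191 went from 78.2 ± 2.55 to 34.6 ± 0.92 CPM. The 7 less abundant genes SGPP2, PADI2, ASTL, TRIM2, CA11, FGF23 and FCMR changed by -1.30, -1.28, -1.25, -1.25, -1.24, -1.22 and -1.18 on the log2 scale. FGF23 rested on control replicate 1 with 544 counts against 270 and 196 in the other controls; without that library its log2 fold change was -0.56. Its adjusted p was 0.0137 with all libraries, 0.0316 without control replicate 1, 0.0661 without MYO6 siRNA replicate 2 and 0.0804 in DESeq2.

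**Figure D2:**
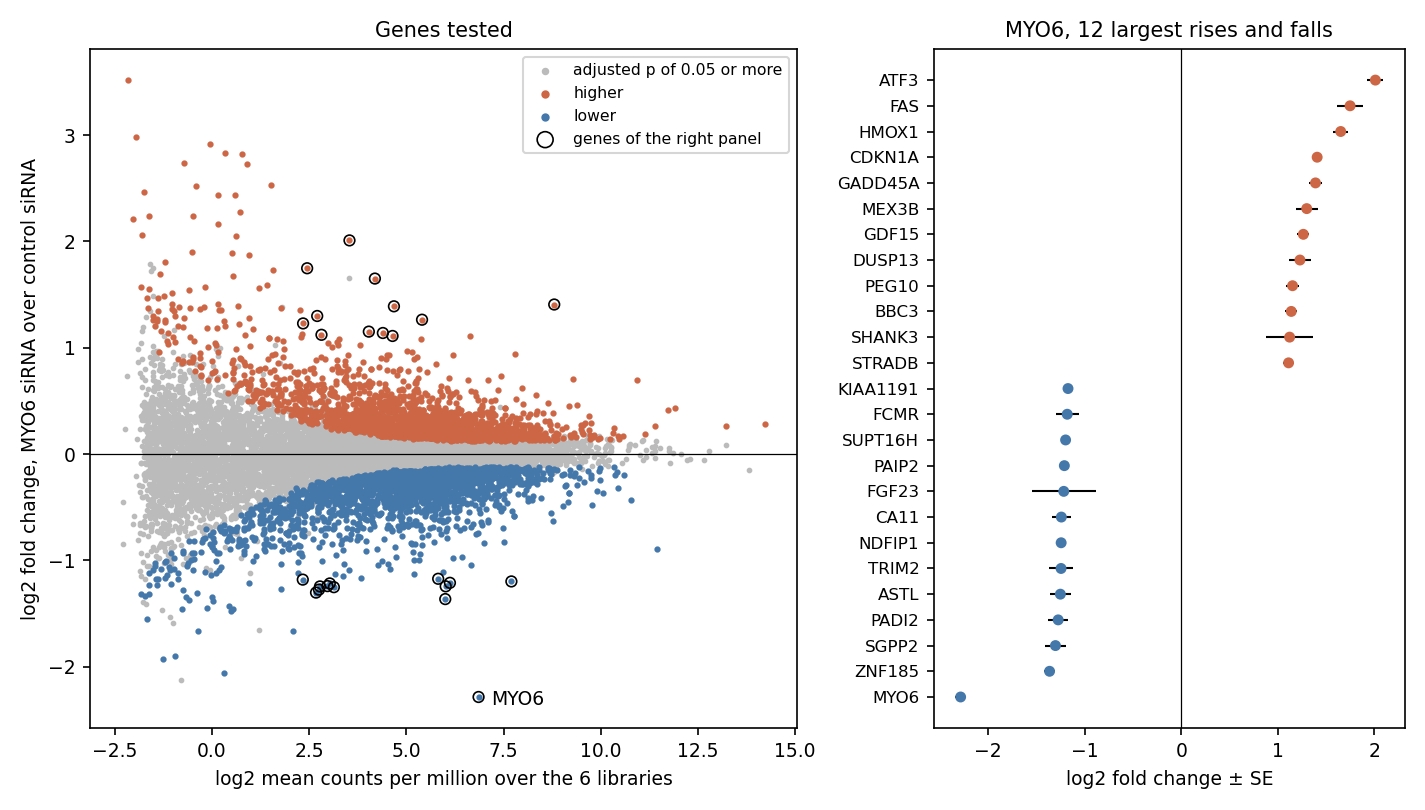
Left, log2 fold change (MYO6 siRNA over control siRNA) against log2 mean CPM for the 14358 genes tested, with genes of an adjusted p under 0.05 coloured by direction. Right, log2 fold change and SE of MYO6 and of the 12 largest rises and 12 largest falls among protein-coding genes of at least 5 CPM without overlap of the groups; they run from -2.29 for MYO6 to 2.01 for ATF3.

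Target genes of the tumour suppressor p53 rose together. Of 30 members, all tested, 24 rose and 0 fell, and the same 24 and 0 passed when adjusted over the list alone. The median log2 fold change of the list was 0.57, and the list's median per library lay between 0.55 and 0.60 in the MYO6 siRNA libraries and between -0.01 and 0.02 in the controls. All 24 genes that rose did so without overlap of the groups, which also held for 4207 of all 4307 genes that passed. Camera gave an adjusted p of 1.16e-42, and 0.0155 with an estimated correlation. Members with the smallest p were CDKN1A, GADD45A, PHLDA3 at 2.16-fold and BBC3. MDM2, the ubiquitin ligase that degrades p53, rose from 152.1 ± 5.45 to 292.8 ± 23.4 CPM. TP53 itself, which was not on the list, fell from 132.6 ± 5.27 to 99.1 ± 1.29 CPM (log2 fold change -0.42 ± 0.05 SE, adjusted p 1.4e-05 in edgeR). MDM2 and TP53 were named after their values were seen. The 6 members that did not pass were RRM2B, POLH, XPC, CCNG1, SESN1 and FDXR, with log2 fold changes between -0.14 and 0.11; RRM2B passed as lower without MYO6 siRNA replicate 3 (adjusted p 0.0377). CCNG1 passed as higher under the effective length offset (0.31 on the log2 scale, adjusted p 0.0157) and with offsets for GC content and length (0.12, adjusted p 0.0412).

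**Figure D3:**
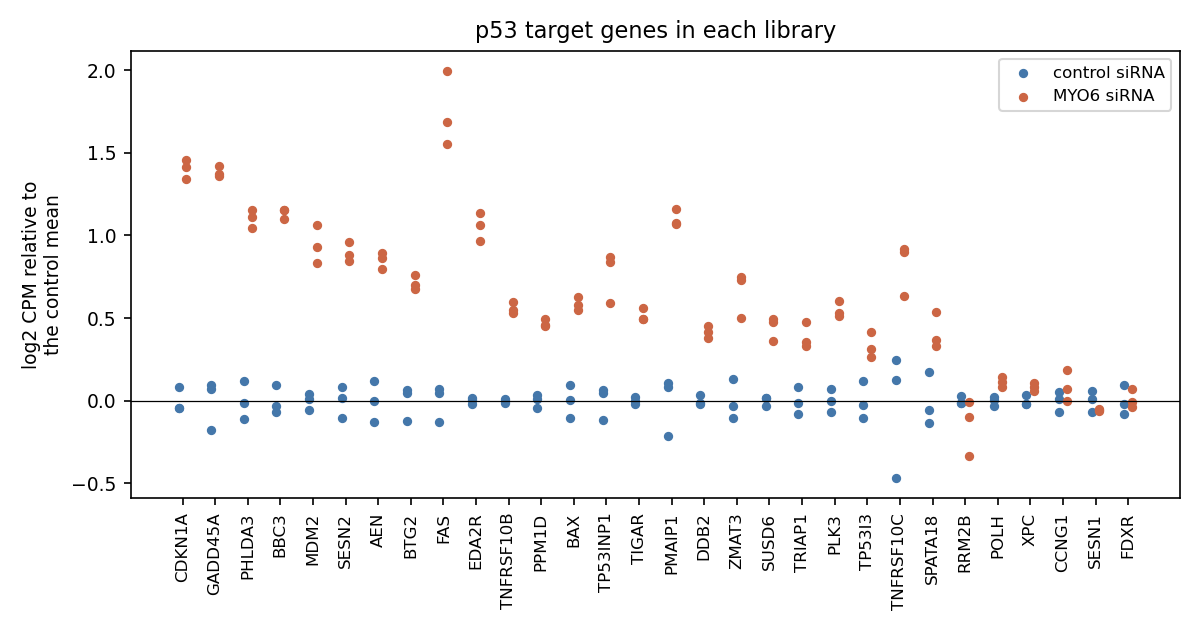
Each of the 30 tested p53 target genes in each library, as log2 CPM relative to the mean of the 3 control libraries, ordered by adjusted p. Points are libraries; the 24 genes that rose show every MYO6 siRNA library above every control library, and the last 6 genes did not pass the test.

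Genes of the unfolded protein response and the ATF4 pathway also rose. Of 29 tested, 17 rose and 2 fell, the same numbers as adjusted over the list alone, with a median log2 fold change of 0.18. The camera adjusted p was 1.62e-07, and 0.0448 with an estimated correlation. ATF3 led, SESN2 rose 1.86-fold, PPP1R15A, which restores translation after stress, 1.65-fold and the chaperone gene DNAJB9 1.45-fold. The call of DNAJB9 was lost on log2(TPM + 1) and log2(TPM + 0.1), at adjusted p-values of 0.0512 and 0.0506 in limma. The 2 members that fell were SLC3A2, at a log2 fold change of -0.29, and PDIA6, at -0.24. HSPA5, the main chaperone of the endoplasmic reticulum, had a log2 fold change of 0.07 and an adjusted p of 0.227 in edgeR.

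Targets of the actin-regulated transcriptional regulators SRF and YAP rose in number, 21 of 29 tested, and 2 fell. Adjusted over the list alone, 22 rose and 4 fell, and the median log2 fold change was 0.35. Camera gave an adjusted p of 2.39e-08, but an adjusted p of 0.224 with an estimated correlation. FLNA, the actin crosslinker filamin A, rose from 1487 ± 76.2 to 2418 ± 70.4 CPM, TPM1, a tropomyosin, rose 1.44-fold, and EGR1 2.55-fold. The 2 cytoplasmic actin genes moved apart. ACTG1 fell from 3643 ± 162 to 1963 ± 13.7 CPM (log2 fold change -0.89 ± 0.05 SE, adjusted p 1.88e-08), whereas ACTB, named after its values were seen, rose from 3300 ± 100 to 4444 ± 43.7 CPM (0.43 ± 0.04 SE, adjusted p 9.91e-06). These 2 genes and their pseudogenes share sequence, so reads between them could be divided wrongly. TAGLN2 was the other member that fell, at a log2 fold change of -0.36.

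Immediate early genes, which growth factors and stress induce within minutes, rose in 14 of 24 tested members and fell in 3, with a median log2 fold change of 0.26. Adjusted over the list alone, 14 rose and 4 fell. Camera gave an adjusted p of 1.85e-07, and an adjusted p of 0.249 with an estimated correlation. FOSL1, a subunit of the AP-1 factor, went from 0.84 ± 0.17 to 4.87 ± 0.36 CPM, a 5.77-fold rise at low abundance, and the p53-regulated gene BTG2 rose 1.64-fold. The members that fell were NR4A2, EGR3 and MCL1, at log2 fold changes of -0.32, -0.35 and -0.24. The list shares EGR1, FOS, JUNB and CCN1 with the SRF and YAP list. It also shares ATF3 with the unfolded protein response list and BTG2 with the p53 list, so these lists are not independent.

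Genes of the G2 phase and mitosis were lower. Of 40 tested, 21 fell and 1 rose, while 21 fell and 2 rose when adjusted over the list alone. The median log2 fold change was -0.15, so most falls were small. Camera gave an adjusted p of 0.00182, and an adjusted p of 0.488 with an estimated correlation. TPX2, a spindle assembly factor, fell from 250.5 ± 10.8 to 172.8 ± 7.12 CPM, and the mitotic kinesin KIF20A and the spindle gene HMMR fell by 0.35 and 0.34 on the log2 scale. The call of HMMR was lost under the effective length offset (adjusted p 0.0586) and on log2(TPM + 1) (adjusted p 0.0536 in limma). The member that rose was FOXM1, a transcription factor of mitotic genes, at a log2 fold change of 0.23. MKI67, a marker of cycling cells, had a log2 fold change of 0.02. The G1/S and DNA replication list did not pass (6 rose and 10 fell of 40, adjusted p 0.521), although GINS1 fell from 60.4 ± 1.55 to 37.2 ± 1.47 CPM.

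Cholesterol synthesis genes were higher in 10 and lower in 2 of 24 tested members, with 12 and 2 when adjusted over the list alone and a median log2 fold change of 0.13. HMGCS1, DHCR24, SC5D and MSMO1 rose 1.35-fold, 1.30-fold, 1.32-fold and 1.25-fold. The camera adjusted p was 0.00784, with an adjusted p of 0.459 with an estimated correlation. Cytosolic ribosomal protein genes passed camera as higher (adjusted p 0.0178), with 13 rises such as RPL32 at 1.22-fold and RPS10 at 1.23-fold and 1 fall, RPS26, among 74. Only 3 rises and 0 falls passed when adjusted over the list alone, and the list had an adjusted p of 0.841 with an estimated correlation and of 0.302 in fry. The call of RPS26 was lost without control replicate 1 or any 1 of the MYO6 siRNA replicates (adjusted p 0.212, 0.0591, 0.139 and 0.148). The list's medians per library overlapped between the groups, at 0.03 to 0.12 with MYO6 siRNA and -0.09 to 0.08 in the controls. The camera call was also lost without control replicate 1, MYO6 siRNA replicate 1 or MYO6 siRNA replicate 2, at adjusted p-values of 0.295, 0.0719 and 0.165.

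Apart from the SRF and YAP list, which is tied to actin and passed as given above, the lists chosen for myosin VI's places of action did not pass camera. These are myosin VI partners, other myosins, RNA polymerase II, clathrin endocytosis, autophagy and lysosome. The estrogen and luminal lists did not pass either, all with all libraries and the default filter. Among estrogen-induced genes, 7 rose and 11 fell of 40 (7 and 12 adjusted over the list alone; camera adjusted p 0.981). STC2 rose from 474.7 ± 28.1 to 776.7 ± 31.5 CPM and TPD52L1 and KCNK5 rose 1.40-fold and 1.69-fold, whereas the amino acid transporter gene SLC7A5 fell from 2003 ± 39 to 1481 ± 55.2 CPM. GREB1 fell by 0.35 on the log2 scale, and the log2 fold change was 0.10 for TFF1 (adjusted p 0.205) and -0.12 for ESR1, the estrogen receptor gene (adjusted p 0.0893). Without control replicate 2 both passed, at adjusted p-values of 0.00333 and 0.0219. ESR1 also passed with offsets for GC content and length and with the replicate number as a block (adjusted p 0.042 in each), so its call depended on the setting. These 3 genes were chosen after their values were seen. Of 24 luminal identity genes and receptor cofactors, 5 rose and 9 fell (adjusted p 0.278), among them MUC1 with a fall from 73.9 ± 6.63 to 43.8 ± 2.52 CPM, SPDEF at -0.49 and the coactivator gene CREBBP at -0.40 on the log2 scale. The direction of CREBBP depended on isoform lengths, with 0.11 under the effective length offset, so its fall is uncertain.

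Of 16 tested genes for myosin VI partners, 4 rose and 6 fell (camera adjusted p 0.498), where 30.0% of all genes tested passed. ARHGEF2, RHOBTB3, TAX1BP1 and TOM1L2 fell by 0.43, 0.36, 0.32 and 0.31 on the log2 scale. Among 19 other myosin heavy chain genes, 5 rose and 2 fell (adjusted p 0.57); MYO5A, MYO1B and MYH9 rose 1.19-fold, 1.16-fold and 1.19-fold and MYO5B fell by 0.20 on the log2 scale. The calls of TOM1L2, MYO5A and MYO5B were lost under the effective length offset. Genes of RNA polymerase II and its general factors rose in 3 and fell in 7 of 37 (adjusted p 0.798), with POLR2D and GTF2A1 lower at -0.43 and -0.53. Clathrin endocytosis genes rose in 5 and fell in 4 of 29 (adjusted p 0.605), with BIN1 1.75-fold higher. Autophagy genes rose in 8 and fell in 3 of 31 (adjusted p 0.388), with the cargo receptor genes SQSTM1 1.37-fold higher and NBR1 lower at -0.32. Lysosome genes rose in 10 and fell in 3 of 29 (adjusted p 0.146), with IDS 1.35-fold and CTSA 1.30-fold higher. That list passed as higher without control replicate 2 (adjusted p 0.0195) and with no filter on low counts (adjusted p 0.048). Camera tests for a common direction, so it can miss lists whose members move both ways. Fry's test for changes in either direction gave adjusted p-values of 3.29e-06 for myosin VI partners, 9.25e-05 for luminal identity and 4.38e-06 for estrogen-induced genes. All lists but ribosomal proteins, mitochondrially encoded genes and leukocyte markers passed it, so it sets none of these 3 apart.

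**Figure D4:**
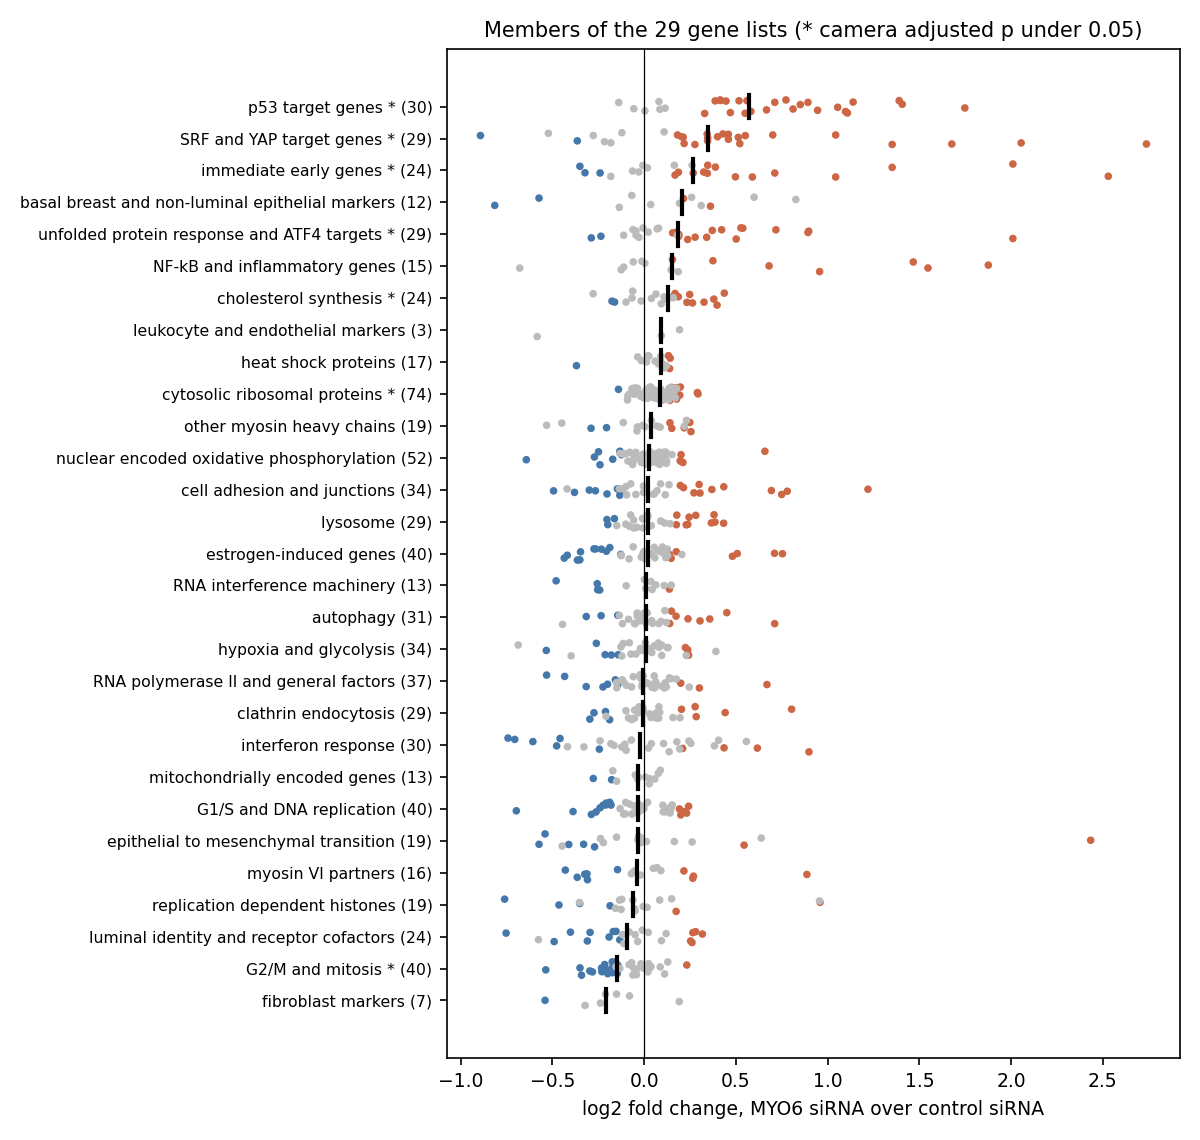
Log2 fold change (MYO6 siRNA over control siRNA) of every tested member of the 29 lists, with the number tested in brackets. Points are genes, coloured where the adjusted p was under 0.05 (orange higher, blue lower) and grey otherwise, black bars are list medians, and a star marks the 7 lists that passed camera; the p53 list has the highest median, 0.57.

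Interferon response genes showed no common direction, with 4 rises and 6 falls among 30 and a camera adjusted p of 0.905. IFITM1, BST2 and USP18 were lower at -0.46, -0.61 and -0.48 on the log2 scale and IRF1 rose 1.53-fold. NF-kB and inflammatory genes had 7 rises and 0 falls among 15 tested but did not pass camera (adjusted p 0.158), which compares members with the other genes. Fry, which asks whether the members move 1 way on balance without that comparison, gave an adjusted p of 0.00361. LIF rose from 0.82 ± 0.14 to 3.04 ± 0.30 CPM and TNFAIP3 from 0.33 ± 0.07 to 1.00 ± 0.06 CPM, both at low abundance. Cell adhesion genes rose in 11 and fell in 8 of 34 (adjusted p 0.388), including laminin genes LAMC1 at 1.62-fold and LAMB1 at 1.35-fold and the integrin gene ITGB5 lower at -0.49. Epithelial to mesenchymal transition genes rose in 2 and fell in 5 of 19 (adjusted p 0.521), with SERPINE1 going from 0.34 ± 0.12 to 1.90 ± 0.27 CPM and COL1A1 and THBS1 lower at -0.54 and -0.41. The call of THBS1 was lost on log2(TPM + 1) and log2(TPM + 0.1), at adjusted p-values of 0.0516 and 0.0526 in limma.

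The remaining lists did not pass camera either. Hypoxia and glycolysis genes rose in 3 and fell in 5 of 34 (adjusted p 0.798), with HK1 lower at -0.53. Heat shock genes rose in 3 and fell in 1 of 17 (0.388), that fall being HSPB1. Nuclear encoded respiratory chain genes rose in 5 and fell in 7 of 52 (0.981), with NDUFS2 lower at -0.64, and mitochondrially encoded genes rose in 0 and fell in 3 of 13 (0.62). Histone genes rose in 2 and fell in 4 of 19 (0.388), a class without poly(A) tails that poly(A) selection captures poorly. RNA interference genes rose in 1 and fell in 4 of 13 (0.518), with DICER1 lower at -0.48. Markers of other cell types had 2 rises and 2 falls of 12 for basal epithelium (0.798), 0 and 1 of 7 for fibroblasts (0.336) and 0 and 0 of 3 for leukocytes and endothelium (0.981). Adjusted over the list alone, rises and falls became 6 and 11 for luminal identity, 5 and 4 for other myosins, 10 and 4 for lysosome, 12 and 9 for cell adhesion, 11 and 11 for G1/S, 7 and 2 for NF-kB, 5 and 5 for the nuclear respiratory chain, 0 and 1 for its mitochondrial part, 3 and 4 for histones and 3 and 2 for basal markers. They stayed as given above for the lists not named there. The median and the mean log2 fold change differed in sign for clathrin endocytosis, epithelial to mesenchymal transition, hypoxia, RNA interference, leukocyte markers and other myosins, lists whose members moved both ways or did not pass. Camera's direction followed the mean in all of these but 2, epithelial to mesenchymal transition and other myosins, where it followed the median.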

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

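The GC and length corrections and the passenger strand test were chosen after the main results were seen.

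Transcripts that the annotation did not match were left out of the gene totals and tested on their own. Of 2613 such transcripts with enough counts, 5 were higher and 10 lower with MYO6 siRNA (0.574%) at an adjusted p under 0.05 in edgeR, which drew attention because the gene comparisons do not use them. No explanation of these was tested.

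Many genes changed. Grouping the 6 libraries by their labels gave 4307 genes, and 1 of the 10 splits into 3 and 3, the real one, gave as many; the highest other split gave 1 gene. With 10 splits no share under 0.05 can arise. Trends with GC content or annotated gene length do not account for most calls. With per-library offsets for both, 96.0% of the genes kept their direction and an adjusted p under 0.05. These offsets use 1 length per gene, so they cannot test effective lengths that differ between libraries. The effective length offset kept 52.8% of the calls, and limma on log2(TPM + 1) kept 44.3%. A part played by those lengths therefore stays open. The labels do not say whether the groups differed in anything besides the siRNA.

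Off-target effects of the siRNA are the first question for 1 sequence. Of 13383 tested genes with an annotated 3' UTR, 1879 carry the 7-base match TAATGAA to the guide's seed. Within deciles of 3' UTR length their median log2 fold change differed from that of genes without it by -0.0102, and 69 of 100 control 7-mers gave a difference as low. Of 2118 lower genes with a 3' UTR, 342 carry the match, where 332 would at like 3' UTR length. The passenger strand's match CCTAAAC gave a difference of -0.00712, with 38 of 100 controls as low. For 8-base matches, which add an A, the difference was -0.00575 for the guide and -0.0277 for the passenger strand, without 8-base controls. The guide's 8-base match lies in 8.17% of lower, 7.3% of higher and 5.69% of unchanged genes, shares not matched for 3' UTR length. These values argue against seed matches in 3' UTRs as the cause of most falls, though single genes such as TRIM2, which has a match, and sites outside 3' UTRs stay open.

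Of the 30 p53 target genes, 24 rose. Trends with GC content or annotated gene length do not account for this. The list's median log2 fold change was 0.57 with the per-library offsets as well as without them, and the camera adjusted p was 4.41e-45 with them. Lowering of another gene by the same siRNA stays open, since 1 siRNA sequence was used. The 342 lower genes with a seed match, near the 332 at like 3' UTR length, are no evidence for it. Such a count cannot clear any single gene, so it does not decide the question. An effect of transfection also stays open if the samples titled WT Control were not transfected. A response to depletion of myosin VI is the biological explanation that the design names, and it was not tested apart from the siRNA; a different siRNA or a rescue would be needed.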

How the results depend on the processing

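The alternatives with GC content and length offsets, without seed-match genes, and without members shared with the p53 list were chosen after seeing the data. MYO6 stayed lower and past the threshold in all 20 settings run for genes, with log2 fold changes from -2.49 to -2.23. The number of genes changed moved by over 1.5 times in 5 settings. The effective length offset gave 2427 (1195 higher, 1232 lower), of which 2276 were among the 4307, and log2(TPM + 1) gave 2051 (827, 1224) and log2(TPM + 0.1) 2031 (820, 1211) in limma; the cause was not tested. By construction, an adjusted p under 0.01 gave 2547 (1242, 1305) and a 1.2-fold null 819 (370, 449). DESeq2 gave 3569 and no count filter 4684. Leaving out 1 library gave 3098 to 4834 genes (1516 to 2416 higher, 1582 to 2418 lower). Without genes that carry the seed match, 3647 genes passed.

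Camera with an estimated correlation kept 2 of the 7 lists, p53 targets and the unfolded protein response; the other list settings gave 6 to 8 lists. The 7 lists of fry were not the same 7, since NF-kB gained a call (0.00361) and the ribosomal proteins lost theirs (0.302). MYO6 left was 17.7% by TPM against 20.5% by CPM. CREBBP reversed under the effective length offset (0.1122) and on TPM (0.08319 and 0.08545), with no call in any of these. Of 2372 values of 119 other named genes, 2325 kept their side of the threshold, 37 lost the call, 7 gained it and 3 reversed. A change of direction without a call in either setting was not counted as reversed. Of 607 list values, 595 kept their side of the threshold, 9 lost the call, 3 gained it and 0 reversed. For lists, a reversal was counted only with a call in both settings.

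Whether equal replicate numbers pair the samples is not known, since no label says so. Deviations from the group means correlated at only 0.037, 0.049 and 0.013 between same-numbered libraries. All 6 libraries nevertheless correlated best with their own number, a weak hint from the data only. Deviations within a group cancel each other, so these matches are not independent. How often they would arise by chance was not computed. With the replicate number as a block, 4588 genes changed (2297 higher, 2291 lower), MYO6 was at -2.28 and 7 lists passed; among the named genes, only ESR1 changed its call (-0.12, adjusted p 0.042). Small changes could be missed. With 3 simulated libraries per group at these library sizes and this spread, the test recovered 39% of 1.2-fold changes. Only 200 of 14358 simulated genes were changed, whereas 30.0% of genes passed in the data. Adjusted p-values depend on that share, so recovery in the data may differ. Recovery at other depths was not tested.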

Other observations

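The tests in this part were chosen after the genes concerned had been seen, with their bounds set before each test was run.

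HMOX1 was among the largest rises, and OSGIN1 and AKR1C3 rose 2.12-fold and 2.04-fold, from 26.4 ± 3.20 to 56.4 ± 1.06 CPM and from 6.19 ± 0.19 to 12.6 ± 0.71 CPM. All 3 are known targets of the transcription factor NRF2. A list of 21 other NRF2 targets was then tested, and 13 rose and 0 fell, with a median log2 fold change of 0.28. Camera gave a p of 1.72e-09, and 0.0157 with an estimated correlation. SRXN1, ME1, NQO1 and the ferritin genes FTH1 and FTL were among the rises, at log2 fold changes of 0.59, 0.54, 0.27, 0.41 and 0.36. GCLC and TXNRD1, at 0.0169 and -0.00289, did not pass, and SLC7A11 is also on the unfolded protein response list. Higher NRF2 activity may be part of the response, a hypothesis that these data do not decide, since the list was written after those 3 genes were seen and NRF2 activity was not measured. AKR1C1, AKR1C2 and AKR1C3 are near-identical in sequence, so their separate values are uncertain.

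G3BP2, which encodes a core protein of stress granules, fell from 137.1 ± 5.89 to 66.5 ± 2.67 CPM and its paralog G3BP1 from 110.2 ± 3.06 to 68.2 ± 1.09 CPM. Their adjusted p-values were 1.01e-08 and 1.61e-07 in edgeR, with no overlap of the groups, as in most genes that passed. Neither carries the guide's seed match in its annotated 3' UTR. They were picked from the table after their values were seen, so they form no tested group.

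PAIP2, NDFIP1 and KIAA1191, 3 of the 12 largest falls, lie on the distal long arm of chromosome 5. Fewer copies of that region in the MYO6 siRNA cultures would lower its other genes too. The 249 other tested genes from position 139341587 to the end of the chromosome had a median log2 fold change of 0.0247, with 45 higher and 23 lower and none lower by 2-fold, which argues against a regional loss.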
